A study of Mus musculus with 8 samples.

How the data were processed

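RNA from the epidermis of B6129 mice was measured on Illumina bead arrays. Per the labels, mice of both sexes aged 7 to 8 weeks had their backs shaved, and 3 days later each received 2 µg of the glucocorticoid fluocinolone acetonide (FA) in 200 µl of acetone on the skin, or acetone without FA (vehicle). Samples were collected 24 hours after this treatment. The design names 2 animals for each of the 4 conditions, so each of the 8 arrays was taken as a separate animal, and replicate numbers have no order. The arrays were grouped by the sex and treatment in the labels.

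The deposited table of unprocessed values holds, per the file headers, an intensity (mean bead signal, not background corrected and not normalized) and a detection p-value for each of 25697 probes on each array. The detection p-value, per the file headers, stands beside each signal and was read as the test of that signal against the array's negative controls. The deposited matrix holds log2 values for 13247 probes. The labels name limma without a version as the authors' tool. Running limma neqc (normexp background correction with an offset of 16, then quantile normalization, with controls inferred from the detection p) on the unprocessed table gave the authors' deposited log2 values to within 5.00e-09. The probes in the matrix were those with a detection p under 0.05 on at least 2 arrays, 13247 of 13247. The scanner software and its settings are not given in the sources used here.

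All values were computed again from the unprocessed table with R 4.3.3 and limma 3.58.1. Probes were kept when detected at p under 0.05 on at least 2 arrays. Of the kept probes, 12476 had 1 gene symbol in the platform table and 771 had none; the latter were left out of the comparisons. Where a gene had several probes (2304 genes), the probe with the highest mean over all arrays stood for it, which left 9416 genes. Bead arrays give no read depth; the number of arrays and the signal over background limit the precision. Each array's signal floor was the lowest log2 value among its detected probes. Where a gene was not above background on any array of 1 of the groups compared, its fold is given as "at least" a value computed against that floor. The same was done where a gene's mean in 1 of the groups lay below the mean floor of that group's arrays. Where this held for both groups, no fold is given.

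The 4 groups were fitted as 4 means in a single limma model (lmFit and eBayes), with 4 residual degrees of freedom and 3.35 prior ones. From it came the FA effect in females, the FA effect in males, the difference of these effects (male minus female, the interaction), their mean, and the difference between sexes (male minus female) in vehicle and in FA. Tests were two-sided, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05 over 9416 genes. Errors written after ± are standard errors from this fit, so they rest on the spread in all 4 groups and not only in those compared. The similarity of the sexes was measured by correlation of FA effects across genes. The size of the response was the SD of FA effects across genes after removal of the replicate error variance. Both are values without a test, given with jackknife errors.

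Before the data were examined, the comparisons, the tests, the alternatives, the rule for naming genes and 28 gene lists were fixed. The lists cover glucocorticoid-induced genes; cell cycle; cornified envelope and barrier proteins; epidermal barrier lipid synthesis; cholesterol synthesis; activated-keratinocyte genes; cytokines and chemokines; interferon-stimulated genes. They also cover circadian clock genes, immediate early and heat shock genes, sex steroid and glucocorticoid receptors and metabolism, extracellular matrix and adhesion, Y-linked genes and X-linked genes that escape inactivation. Marker lists stand for basal and suprabasal keratinocytes, the anagen hair follicle and hair shaft, the follicle bulge and upper follicle, the sebaceous gland, Langerhans and dendritic cells, dendritic epidermal T cells and melanocytes. The remaining marker lists are dermal fibroblast, skeletal muscle, adipocyte, endothelial cell, erythrocyte, and neutrophil, macrophage and mast cell. Lists with at least 5 measured genes (3 for the sex chromosomes) were tested with limma camera at a preset correlation of 0.01 between genes, adjusted over the 25 lists tested. Camera compares a list with all other genes. Camera with an estimated correlation and fry, which tests whether a list's genes move on balance in 1 direction, were run beside it. For each list, the members that passed are counted over all genes and after adjustment over the list alone.

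Named genes follow this rule: in each comparison, the 10 largest rises and 10 largest falls among genes that passed and whose arrays did not overlap between the groups, or the 5 smallest p in a direction where none passed. Added to these are up to 4 members of each list with the smallest p, and any glucocorticoid-induced or sex-chromosome gene. Symbols that are only clone or locus names are counted but not named. Genes outside the rule are named as chosen after their values were seen.

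The alternatives were: quantile-normalized log2 of the signal without background correction, median scaling, an offset of 50, the deposited values, no filter, detection at p under 0.01 on at least 4 arrays, the mean of all detected probes of a gene, replicate number as a block, array weights, eBayes with trend and robust, a 2-fold minimum, only the arrays of the groups compared, and each array left out in turn. A skeletal muscle score as covariate and a restriction to genes detected on all 8 arrays were added after seeing the data. So were the rules that leave the tests of muscle carry-over and of the hair follicle undecided in the closing section. The muscle score is the mean of the muscle list's own genes, so it removes that list's change by construction. Genes detected on all 8 arrays leave out those that FA took below background, so lost calls for falls are in part built in. The steps were tested on simulated data with 200 genes changed in 1 sex: for a log2 change of 2, 95.5% were recovered in that sex and 62.7% as a difference between sexes, and for a log2 change of 1 the shares were 34.3% and 4.48%. Of 9216 unchanged genes, 5 were called. Camera called 3% of lists without a planted shift and 100% of lists of 20 genes shifted by 0.5 on the log2 scale. The simulation drew genes independently, with the same spread on every array. Its shares therefore do not carry over to lists whose genes vary together or to the more variable female FA arrays. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.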

Results

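The data are 8 bead arrays of mouse epidermis, 2 each from females given vehicle, females given FA, males given vehicle and males given FA. FA is a synthetic glucocorticoid, a class of drug used on skin against inflammation. Between 44.5% and 46.9% of the 25697 probes were detected on 7 of the arrays, and 32.4% on female FA replicate 2, whose median signal before normalization was 191 against 99.5 to 109 on the others. Its floor was 5.88 on the log2 scale against 4.90 to 4.99. Partner arrays of a group correlated at 0.990 (female vehicle), 0.959 (female FA), 0.989 (male vehicle) and 0.986 (male FA) across genes. The number of arrays, 2 per group, limits the precision of every value.

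The comparison of FA with vehicle in females asks what a glucocorticoid does to the epidermis of this sex a day after 1 application. Both Fkbp5 and Pdk4 of the fixed glucocorticoid-induced list were among the 10 largest rises. Fkbp5, a co-chaperone of the glucocorticoid receptor, rose 13.5-fold (log2 3.75 ± 0.23, SE, n = 2 arrays per group). Pdk4, a kinase that limits the entry of pyruvate into mitochondria, rose at least 16.1-fold, with its vehicle mean below the floor. Serpina3n, a protease inhibitor with near-identical paralogs, rose 23.2-fold (4.54 ± 0.23). Uhrf1, which maintains DNA methylation, was at least 17.2-fold lower and Mcm5, a subunit of the replicative helicase, at least 11.8-fold lower, both with means below the floor in FA.

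Other large rises in females were Spsb1 (log2 4.38 ± 0.22), Sectm1b (4.03 ± 0.24), Hs3st3a1 (at least 14.6-fold), Fam180a (3.59 ± 0.28), the stress gene Gadd45g (3.54 ± 0.19) and Spink2 (3.39 ± 0.24). Best2, a chloride channel gene, was not above background in vehicle and was at least 16.5-fold higher with FA. Among the falls, Akr1c18, which inactivates progesterone, was not above background with FA and at least 21.8-fold lower, and its paralog Akr1c19 was at least 6.23-fold lower. Mcm2 was at least 6.73-fold lower, and Stfa1, a cystatin with near-identical paralogs, at least 13.3-fold lower. Panx3, above background on 1 of the 2 female FA arrays, fell by 3.91 ± 0.57. The interferon-induced Ifitm3 fell by 3.35 ± 0.26, and so did the histone genes H2ac12 (-3.58 ± 0.31) and H2ac15 (-3.30 ± 0.39), which have near-identical paralogs. In all, 944 of 9416 genes passed in limma (10.03%), 430 higher and 514 lower, and 608 of them changed at least 2-fold.

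The split by direction depends on scaling: with median scaling, 565 genes were higher and 450 lower, and the median change of all genes moved from -0.04 to 0.16. In genes detected on all 8 arrays, which leave out genes that FA took below background, 686 were higher and 575 lower. Leaving out 1 array at a time, the count was 216 and 222 without female vehicle replicate 1 and 2, 3004 without female FA replicate 1, 535 without either male vehicle array, 616 without either male FA array and 822 without female FA replicate 2.

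The fixed lists show which processes moved in females. Of 32 glucocorticoid-induced genes measured, 22 rose and none fell (24 and 0 when adjusted over the list alone), with a median change of 1.27 (camera adjusted p = 2.49e-18). The call held with an estimated correlation (adjusted p = 0.0142). Txnip, an inhibitor of thioredoxin, rose by 2.88 ± 0.15, the mTOR inhibitor Ddit4 by 2.76 ± 0.24, the cytochrome Cyp2b10 by 2.89 ± 0.25 and Tsc22d3, a mediator of glucocorticoid effects on inflammation, by 2.42 ± 0.26. The rest that rose ran from Angptl4 (2.22), Sesn1 (2.13), Klf9 (2.07), Glul (2.07), Pik3r1 (1.99) and Ccn2 (1.97) down to Nfkbia (0.70). Cebpb (0.02), Anxa1 (0.35) and Gadd45a (-0.46) did not pass.

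Of 24 cell cycle genes, 10 fell and none rose (11 lower and 1 higher when adjusted over the list alone), with a median of -0.90 (adjusted p = 2.19e-05; adjusted p = 0.457 with an estimated correlation). Mcm4 fell by 1.82 ± 0.19 and the licensing factor Cdt1 by 2.48 ± 0.23. In genes detected on all 8 arrays this list's call was also lost. Those are 11 of the 24, without genes that FA took below background such as Mcm2, so the loss is partly built in. Of 18 cholesterol synthesis genes, 7 fell (11 when adjusted over the list alone), with a median of -0.92 (adjusted p = 5.75e-05; adjusted p = 0.457 with an estimated correlation). Fdps fell by 1.68 ± 0.18, the rate-controlling squalene epoxidase gene Sqle by 1.42 ± 0.20, Lss by 1.69 ± 0.26 and Insig1 by 1.66 ± 0.28. Of 14 Langerhans and dendritic cell markers, 7 fell (11 lower and 2 higher when adjusted over the list alone), with a median of -1.34 (adjusted p = 6.81e-05; adjusted p = 0.457 with an estimated correlation). Among these were the antigen-presentation genes H2-Ab1 (-3.08 ± 0.31) and H2-Eb1 (-2.56 ± 0.29) and their activator Ciita (at least 2.64-fold lower). Markers of dendritic epidermal T cells moved with them: 5 of 16 fell (7 when adjusted over the list alone), among them Thy1 (-1.47 ± 0.20) and Cd3g (-1.02 ± 0.22), with a median of -0.32 (adjusted p = 0.0356; adjusted p = 0.457 with an estimated correlation). The T cell call was lost without female vehicle replicate 1 (adjusted p = 0.0797), without female FA replicate 1 (0.167), with median scaling and with the mean of all probes.

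Sebaceous gland markers had a median of -0.74 in females, with 1 of 17 higher and 4 lower (2 and 10 when adjusted over the list alone; adjusted p = 0.0218; adjusted p = 0.639 with an estimated correlation). Mgst1 fell by 2.76 ± 0.47, the fatty acid elongase Elovl6 by 1.82 ± 0.29 and the desaturase Scd1 by 1.48 ± 0.34, while Fads1 rose by 1.52 ± 0.18. Without female vehicle replicate 2 the call was lost (adjusted p = 0.0646). Skeletal muscle markers had a median of -1.48 with none of 16 past the threshold over all genes or when adjusted over the list alone (adjusted p = 5.11e-04; adjusted p = 0.639 with an estimated correlation). Myl1 had -2.56 ± 0.69 and Mylpf -1.46 ± 0.43. The median for cornified envelope proteins was 0.27, with 1 of 37 genes higher, Sprr1a, which has near-identical paralogs (none when adjusted over the list alone; adjusted p = 0.01005; adjusted p = 0.457 with an estimated correlation). Immediate early and heat shock genes had a median of 0.41, with Hspb1 (0.95 ± 0.19) and the mRNA-decay factor Zfp36 (1.02 ± 0.21) higher of 16 (4 when adjusted over the list alone; adjusted p = 0.0173; adjusted p = 0.457 with an estimated correlation). Without female FA replicate 1 the cornified (adjusted p = 0.0917) and immediate early (0.252) calls were lost, and the former also with median scaling and in genes detected on all 8 arrays. With values below an array's floor set to that floor, the medians became -0.46 for cell cycle, -0.70 for cholesterol synthesis, -1.07 for Langerhans cells and -1.05 for muscle. The floor of female FA replicate 2 was the highest, so this setting by itself raises undetected genes with FA in females.

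The other lists did not pass in females, though some members did. Krt1, a keratin of the differentiating layers, fell by 3.05 ± 0.22 and was the suprabasal marker of 10 that passed. Krt5, a keratin of the basal layer, fell by 1.62 ± 0.21 while the integrin Itga6 rose by 0.97 ± 0.20, among 8 basal markers. Among 20 cytokines and chemokines, Il33 (-1.85 ± 0.19) and Il34 (-1.62 ± 0.39) fell, and Tnfsf11 (at least 3.16-fold) and Ccl27a (1.23 ± 0.25) rose. Of 15 clock genes, Nfil3 (2.19 ± 0.25) and Per1 (1.31 ± 0.26) rose, and Per3 (-1.29 ± 0.22) and Dbp (-1.17 ± 0.28) fell. Igtp (at least 1.94-fold) and Gbp2 (at least 2.10-fold) were the interferon-stimulated genes of 20 that fell, and Defb14 rose by 1.08 ± 0.19 as Cd44 (-1.08 ± 0.23) and Stfa1 fell among 17 activated-keratinocyte genes. Barrier lipid genes went both ways, with 3 of 20 higher and 2 lower, such as Aloxe3 (1.21 ± 0.19) and the ceramidase Acer1 (-1.43 ± 0.16). So did matrix and adhesion genes, with 4 of 26 higher and 3 lower, such as Itga3 (1.18 ± 0.24) and Mmp9 (-1.09 ± 0.23). In the steroid list 3 of 15 fell: Akr1c18, Fkbp4 (-0.97 ± 0.15) and Tspo (-1.01 ± 0.19). Of 14 fibroblast markers, Thbs2 (-2.96 ± 0.41) and Vim (-1.63 ± 0.40) fell, and Lox passed as higher with both group means below the floor, so no fold is given. Sostdc1 (-2.46 ± 0.54) and Krt79 (-2.96 ± 0.72) fell among 9 bulge and upper follicle markers, and C1qa was at least 3.09-fold higher among 10 neutrophil, macrophage and mast cell markers. None of the 7 anagen, 7 endothelial, 3 Y-linked or 5 X-linked genes passed. Adjusted over the list alone, the higher and lower counts of these lists, in the order given, were 0 and 2 (suprabasal), 2 and 1 (basal), 2 and 3, 4 and 2, 0 and 4, 2 and 5, 4 and 3, 4 and 4, 0 and 3, 1 and 2, 0 and 2, 1 and 0, then none except 1 Y-linked gene higher. The matrix list had a median of 0.15, a mean of -0.13 and a test direction of up, and the barrier lipid list -0.05, -0.12 and up. The Y-linked list had -0.05, 0.25 and up, and the neutrophil list -0.07, 0.28 and up. Median scaling turned the medians of activated-keratinocyte genes (-0.28 to 0.29), cytokines (-0.13 to 0.31), interferon-stimulated genes (-0.16 to 0.23) and follicle bulge markers (-0.42 to 0.14). Setting values to the floor turned the same medians (to 0.40, 0.31, 0.35 and 0.19) and those of fibroblast (-0.46 to 0.06), Y-linked (-0.05 to 0.53) and neutrophil and macrophage markers (-0.07 to 0.53). A gene below the floor on every female array gains 0.53 by construction, through the high floor of female FA replicate 2. These turns at the floor therefore decide no direction. The lists too short for a test held Gpnmb, which rose by 3.37 ± 0.17 (melanocyte, 1 of 3), the haemoglobin gene Hba-a1, which fell by 2.71 ± 0.30 (erythrocyte, 1 of 2), and no passing adipocyte gene of 4.

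The comparison in males asks the same of the other sex. Fkbp5 rose 19.4-fold (log2 4.28 ± 0.23, SE, n = 2 arrays per group) and Pdk4 13.9-fold (3.80 ± 0.21). The androgen-regulated protease gene Tmprss2 was not above background in vehicle and was at least 16.3-fold higher. Stfa1 fell 57.7-fold (-5.85 ± 0.91), the gut-hormone gene Pyy 20.6-fold (-4.36 ± 0.71) and Uhrf1 13.6-fold (-3.76 ± 0.43). Partner arrays differed widely for 2 of these genes. The SD in male vehicle and male FA was 1.81 and 1.32 for Stfa1, and 1.71 and 0.16 for Pyy. Pyy was above background on 1 of the 2 male FA arrays. H2-Ab1, an antigen-presentation gene, fell 8.67-fold (-3.12 ± 0.31).

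Spsb1 (3.36 ± 0.22), Sectm1b (3.34 ± 0.24) and Hs3st3a1 (3.25 ± 0.19) also rose in males, as did Defb8 (5.09 ± 1.02) and Mup2 (3.50 ± 0.81), both with near-identical paralogs. The SD in male vehicle and male FA was 1.37 and 1.95 for Defb8, and 0.13 and 1.60 for Mup2. Best2 was at least 11.1-fold and Cdo1, an enzyme of cysteine breakdown, at least 10.3-fold higher. Mmp3, a matrix protease, was at least 9.56-fold lower. Mcm5 (-3.29 ± 0.29) and Ifitm3 (-3.09 ± 0.26) fell, and so did the histone genes H2ac22 (-3.33 ± 0.30), H2ac10 (-3.10 ± 0.28) and H2ac7 (-3.03 ± 0.22), which have near-identical paralogs. In all, 771 of 9416 genes passed (8.19%), 378 higher and 393 lower, and 534 of them changed at least 2-fold. The split was 337 higher and 461 lower with median scaling, and 554 higher and 486 lower in genes detected on all 8 arrays. The count was 261 and 208 without male vehicle replicate 1 and 2, 264 and 242 without male FA replicate 1 and 2, 482 without either female vehicle array and 1497 without either female FA array.

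Glucocorticoid-induced genes had 21 of 32 higher and none lower in males (26 and 0 when adjusted over the list alone), with a median of 1.49 (camera adjusted p = 8.07e-20; adjusted p = 0.0122 with an estimated correlation). Ddit4 rose by 3.05 ± 0.24, Cyp2b10 by 2.96 ± 0.25, Txnip by 2.73 ± 0.15, Tsc22d3 by 2.25 ± 0.26 and Per1 by 1.72 ± 0.26. Cell cycle genes had 10 of 24 lower (16 lower and 1 higher when adjusted over the list alone), among them Mcm2 (-2.46 ± 0.20) and Mcm4 (-1.85 ± 0.19), with a median of -1.33 (adjusted p = 1.99e-09; adjusted p = 0.240 with an estimated correlation). Mcm2 was above background on 1 of the 2 male FA arrays. Cholesterol synthesis had 4 of 18 lower (4 when adjusted over the list alone), among them Fdps (-1.14 ± 0.18) and Stard4 (-1.37 ± 0.24), with a median of -0.45 (adjusted p = 0.00314; adjusted p = 0.405 with an estimated correlation).

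Langerhans and dendritic cell markers had 8 of 14 lower and 1 higher in males (11 and 1 when adjusted over the list alone), among them H2-Eb1 (-2.89 ± 0.29) and H2-Aa (-2.36 ± 0.30), with a median of -1.68 (adjusted p = 5.72e-07; adjusted p = 0.332 with an estimated correlation). T cell markers had 5 of 16 lower (8 when adjusted over the list alone), among them Thy1 (-2.37 ± 0.20) and Cd52 (-1.72 ± 0.18), with a median of -0.68 (adjusted p = 7.86e-04; adjusted p = 0.240 with an estimated correlation). Interferon-stimulated genes had 5 of 20 lower (8 lower and 1 higher when adjusted over the list alone), such as the immunoproteasome gene Psmb9 (-1.21 ± 0.19) and Oasl2 (at least 3.69-fold lower), with a median of -0.58 (adjusted p = 9.17e-04; adjusted p = 0.332 with an estimated correlation). Cytokines and chemokines had 3 of 20 lower and 1 higher (7 and 2 when adjusted over the list alone). Il33 fell by 2.20 ± 0.19, Ccl4 was at least 2.70-fold lower and Ccl27a rose by 1.21 ± 0.25, with a median of -0.52 (adjusted p = 0.00475; adjusted p = 0.240 with an estimated correlation). Activated-keratinocyte genes had 4 of 17 lower and 1 higher (6 and 1 when adjusted over the list alone), among them the wound keratin Krt17 (-1.24 ± 0.15) and Cd44 (-1.42 ± 0.23), with a median of -0.47 (adjusted p = 0.00667; adjusted p = 0.553 with an estimated correlation). Without male vehicle replicate 2, whose mean for this list was 8.63 on the log2 scale against 7.44 on its partner, the activated-keratinocyte call was lost (adjusted p = 0.211). The calls for these keratinocyte, cytokine and interferon lists and for cholesterol synthesis were also lost in genes detected on all 8 arrays, and the keratinocyte and cytokine calls with the stricter detection filter.

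Fibroblast markers had 2 of 14 lower and 1 higher in males (4 and 1 when adjusted over the list alone): Thbs2 fell by 2.70 ± 0.41, the matrix proteoglycan gene Lum was at least 2.43-fold lower and Lox rose by 0.94 ± 0.21, with a median of -1.27 (adjusted p = 9.17e-04; adjusted p = 0.358 with an estimated correlation). Skeletal muscle markers had 1 of 16 higher (1 when adjusted over the list alone), Actn3 (1.89 ± 0.43), with a median of 1.40 (adjusted p = 2.52e-04; adjusted p = 0.553 with an estimated correlation). Without male FA replicate 2 this median fell to 0.89. In genes detected on all 8 arrays the muscle call in males was lost. A muscle score as covariate ended it in both sexes, by construction, since the score is the mean of these genes. Anagen and hair shaft markers had a median of 0.76, with Krt27 of 7 at least 2.29-fold higher (3 when adjusted over the list alone; adjusted p = 0.0149; adjusted p = 0.355 with an estimated correlation). Immediate early and heat shock genes had a median of 0.38, with Zfp36 (1.02 ± 0.21) of 16 higher (4 when adjusted over the list alone; adjusted p = 0.0153; adjusted p = 0.358 with an estimated correlation). The anagen call was lost without male vehicle replicate 1 (adjusted p = 0.0564), and the immediate early call without male vehicle replicate 2 (adjusted p = 0.0510) and in genes detected on all 8 arrays. At the floor the medians were 0.53 for anagen, -0.36 for cytokines and -0.47 for interferon-stimulated genes.

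Lists that did not pass in males held these changes. Krt1 fell by 2.96 ± 0.22 among 10 suprabasal markers, and Dst (1.44 ± 0.28) and Krt15 (0.76 ± 0.16) rose among 8 basal markers. Nfil3 (2.17 ± 0.25) and Per1 rose and Dbp (-1.77 ± 0.28) and Bhlhe40 (-1.49 ± 0.26) fell among 15 clock genes. Mc5r (at least 2.28-fold) and the lipid-droplet gene Cidea (1.48 ± 0.35) were among 3 that rose of 17 sebaceous markers, whose median was 0.12. Sprr1a fell by 1.22 ± 0.22 among 37 cornified envelope genes, Aloxe3 rose (1.18 ± 0.19) and Acer1 fell (-0.97 ± 0.16) among 20 barrier lipid genes, and Mmp3, Mmp9 (-1.58 ± 0.23) and Timp1 (at least 2.50-fold lower) were among 4 matrix genes of 26 that fell, with Lox rising. Akr1c18 was at least 2.04-fold lower, and Fkbp4 (-0.84 ± 0.15) and Tspo (-0.87 ± 0.19) fell, among 15 steroid genes. Adgre1 fell by 1.75 ± 0.38, Mrc1 was at least 1.27-fold lower and the neutrophil enzyme gene Mpo rose by 1.16 ± 0.24 among 10 neutrophil, macrophage and mast cell markers. Krt15 was the bulge marker of 9 that passed, and no endothelial, Y-linked or X-linked gene did. Adjusted over the list alone, the higher and lower counts were 1 and 2 (suprabasal), 3 and 2, 4 and 2, 5 and 0, 0 and 1, 2 and 3, 2 and 8, 0 and 3, 2 and 2, 2 and 1, then none. At the floor the median of neutrophil and macrophage markers turned from 0.12 to -0.05. In the lists too short for a test, Gpnmb rose by 2.73 ± 0.17, Hba-a1 fell by 1.84 ± 0.30 and the adipocyte gene Car3 rose by 0.88 ± 0.21.

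**Figure D1:**
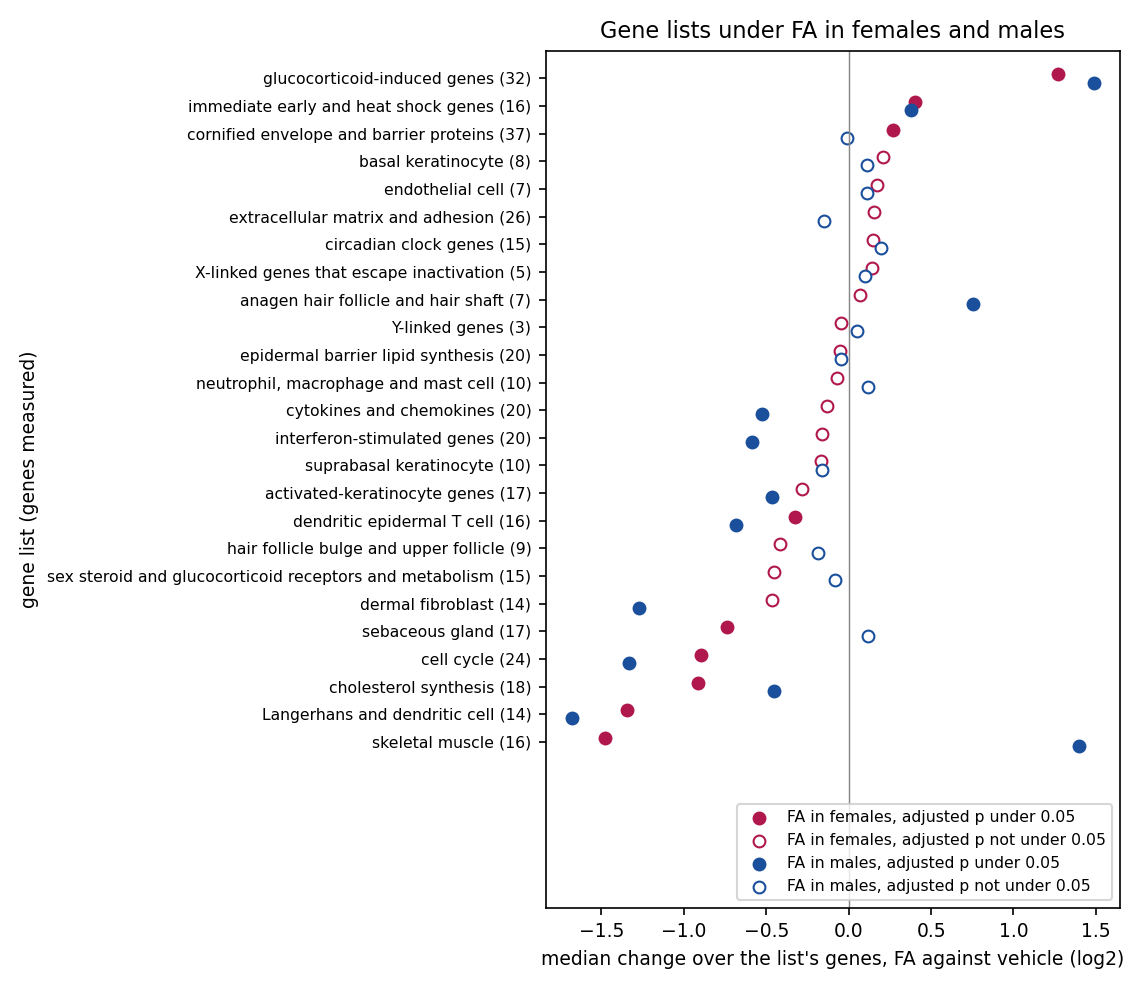
Median change with FA (log2, x axis) of each tested list (y axis, genes measured in parentheses) in females (red) and males (blue), 2 arrays per group. Filled points passed camera at the preset correlation; glucocorticoid-induced genes lie at 1.27 and 1.49, and skeletal muscle at -1.48 and 1.40.

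The mean of both sexes gives the FA effect shared by females and males with 4 arrays on each side. Fkbp5 rose 16.2-fold (log2 4.01 ± 0.16), Spsb1 14.6-fold (3.87 ± 0.16) and Serpina3n 12.4-fold (3.63 ± 0.16). Ifitm3 (-3.22 ± 0.18), H2-Ab1 (-3.10 ± 0.22) and Krt16, a wound keratin (-3.09 ± 0.64), fell. Stfa1, Uhrf1 and Mcm5 passed as lower and Pdk4 as higher, with no value given because their mean in 1 female group lay below the floor. In all, 1955 genes passed, 885 higher and 1070 lower, against 1087 higher and 964 lower in genes detected on all 8 arrays. Lists that passed were glucocorticoid-induced (26 of 32 higher, median 1.28, camera adjusted p = 8.80e-19; adjusted p = 0.0136 with an estimated correlation), cell cycle (12 of 24 lower and 1 higher, -1.14), cholesterol synthesis (10 of 18 lower, -0.72), Langerhans cell (10 of 14 lower and 2 higher, -1.67), T cell (9 of 16 lower, -0.61), interferon-stimulated (7 of 20 lower and 1 higher, -0.34), fibroblast (4 of 14 lower and 1 higher, -0.82) and immediate early genes (4 of 16 higher, 0.48). With an estimated correlation the calls after the first were lost (adjusted p = 0.364 for cell cycle, cholesterol, Langerhans, T cell and immediate early, 0.441 for interferon and 0.517 for fibroblast). When adjusted over the list alone, the higher and lower counts were 26 and 1, 2 and 18, 0 and 12, 2 and 12, 1 and 9, 1 and 8, 1 and 6, and 8 and 0, in the order listed. The fibroblast call was lost without male FA replicate 1 (adjusted p = 0.0731), without male vehicle replicate 1 (0.0641) and with the stricter detection filter. The interferon call was lost without female FA replicate 1 (adjusted p = 0.0664), with median scaling and in genes detected on all 8 arrays. The gene count was 1008, 1084, 1050, 1021, 1198 and 1121 without female vehicle replicates 1 and 2, male vehicle replicates 1 and 2 and male FA replicates 1 and 2, and 3585 without female FA replicate 1.

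Both sexes changed many of the same genes in the same direction. The overlap was 249 genes higher in both, against 17.3 expected for independent sets, and 247 lower in both, against 21.5. Calls in both sexes used the same estimate of each gene's spread, which by itself can raise the overlap above these expected numbers. Of the genes that passed in at least 1 sex, 1169 of 1217 (96.1%) had the same sign in both, and over all 9416 genes 69.7% did. Of the 180 genes that passed as higher in females alone, 173 were also above 0 in males, and of the 266 lower in females alone, 251 were below 0 in males. FA effects correlated across genes at r = 0.676 (Spearman rho = 0.564; jackknife SE of r 0.166), where genes are not independent replicates. The SD of FA effects was 0.555 in females and 0.547 in males, a ratio of 1.02 (jackknife SE 0.606), so a difference in the size of the response was not detectable with these arrays. Without female FA replicate 1 and 2, r was 0.517 and 0.756.

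Hamp2, a hepcidin gene, and Sprr1a were exceptions, the former chosen after its values were seen. Hamp2 fell by 1.39 ± 0.31 in females and rose by 1.45 ± 0.31 in males, and Sprr1a rose by 0.90 ± 0.22 in females and fell by 1.22 ± 0.22 in males. The tests of the difference did not pass for Hamp2 (2.84 ± 0.44, adjusted p = 0.328) or Sprr1a (-2.11 ± 0.31, adjusted p = 0.328).

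**Figure D2:**
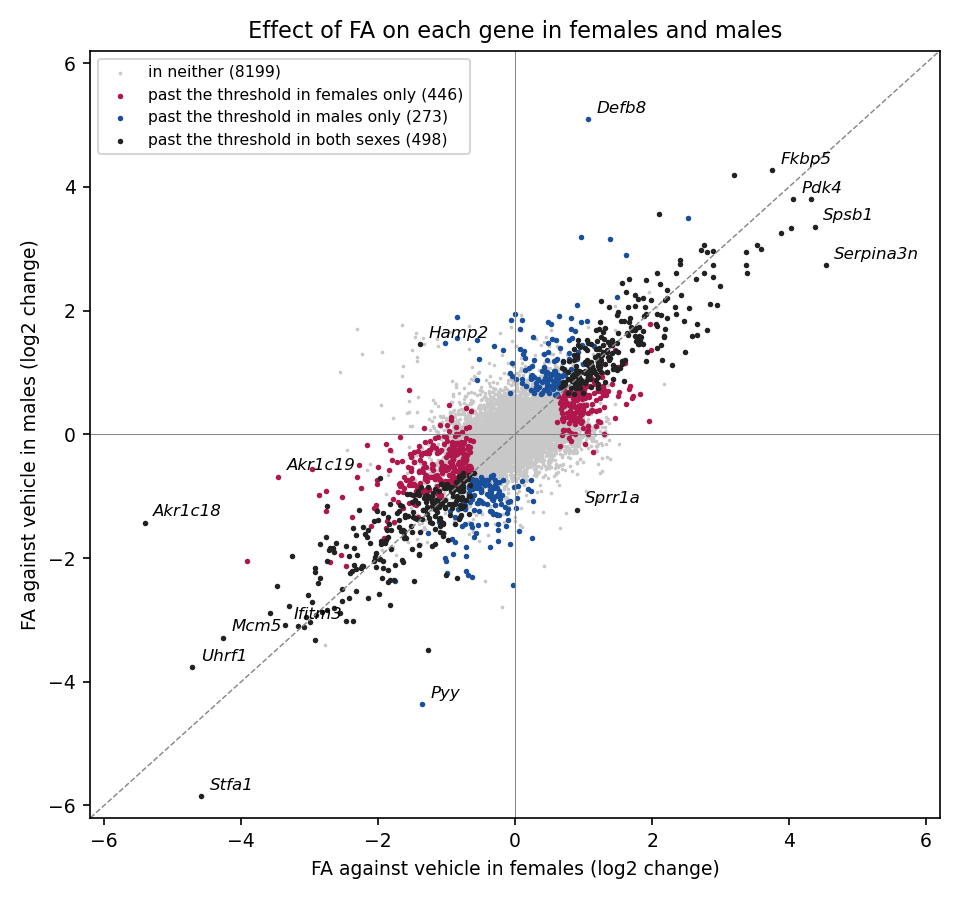
Log2 change with FA in females (x axis) and males (y axis) for 9416 genes, 2 arrays per group; the dashed line marks equal change and colours mark where a gene passed. Of the genes that passed in at least 1 sex, 1169 of 1217 had the same sign in both, and 249 passed as higher and 247 as lower in both sexes.

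The difference of FA effects, male minus female, is the direct test of sexual dimorphism in the response. Akr1c18 and Akr1c19, related aldo-keto reductase genes, passed with a larger fitted fall in females. For Akr1c18 the difference was 3.98 ± 0.32 on the log2 scale (limma adjusted p = 0.0352), with FA effects of at least 21.8-fold lower in females and at least 2.04-fold lower in males. For Akr1c19 it was 2.78 ± 0.26 (adjusted p = 0.0451), with an FA effect of at least 6.23-fold lower in females and a vehicle signal in males of 5.10 on the log2 scale, near the floor. With FA neither gene was above background on any array of either sex, so both differences rest on signals that could not be read. Which sex had the larger fall was therefore not measured. In vehicle the sex differences were -3.93 ± 0.23 for Akr1c18 and -2.97 ± 0.18 for Akr1c19. These were the only genes of 9416 to pass, while 618 had an unadjusted p under 0.05. In the direction of a lower value in males, the smallest p were those of Sprr1a, Mgarp (-1.47 ± 0.23), the chemokine Ccl4 (-1.70 ± 0.28), Ephb1 (-1.34 ± 0.22) and Serpina3n (-1.81 ± 0.32), with adjusted p from 0.328 to 0.497. Mgarp and Ccl4 were not above background with FA in either sex, nor was Ccl4 in female vehicle.

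The calls of Akr1c18 and Akr1c19 held without female FA replicate 2 (adjusted p = 0.00917 and 0.0150). Without female vehicle replicate 1 or 2, male vehicle replicate 1 or 2, or male FA replicate 1 or 2, none passed, and without female FA replicate 1, which leaves the array with the fewest detected probes as the female FA group, 1135 genes did. None passed with median scaling (adjusted p = 0.220 for Akr1c18 and 0.257 for Akr1c19), without the filter (0.0663 for both), with replicate number as a block (0.0935 for both) or with a muscle score as covariate. Genes detected on all 8 arrays exclude both.

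Of the 25 lists tested, 10 differed between sexes in their response to FA in camera, and none with an estimated correlation. Glucocorticoid-induced genes did not: their median difference was -0.02 and mean 0.01, with a test direction of up (adjusted p = 0.947). Skeletal muscle markers had the largest median difference, 2.80 (adjusted p = 6.72e-14; adjusted p = 0.383 with an estimated correlation; 13 of 16 higher when adjusted over the list alone), with -1.48 in females and 1.40 in males. Pvalb had -2.23 and 1.30, and Mylpf -1.46 and 1.57. Sebaceous gland markers had a difference of 1.12 (adjusted p = 3.45e-06; adjusted p = 0.383 with an estimated correlation; 5 higher and 1 lower of 17 when adjusted over the list alone), with -0.74 in females and 0.12 in males. The lipid-droplet gene Cidea had -1.02 and 1.48. Without female FA replicate 2 the sebaceous difference was 0.69. Cholesterol synthesis had a difference of 0.34 (adjusted p = 0.0128; adjusted p = 0.476 with an estimated correlation), with Insig1 at -1.66 and -0.44.

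The other 7 lists had negative median differences. They were cornified envelope (median difference -0.23, adjusted p = 0.00101), activated-keratinocyte genes (-0.52, 0.00466), cytokines (-0.24, 0.00308), interferon-stimulated genes (-0.38, 0.0325), matrix and adhesion (-0.36, 0.00308), T cell (-0.19, 0.0385) and fibroblast markers (-0.62, 0.0111). With an estimated correlation these had adjusted p = 0.383, 0.521, 0.383, 0.476, 0.383, 0.476 and 0.476. Over all genes no member of any of the 10 passed as a difference. When adjusted over the list alone, 1 gene was lower in each of the cornified, cytokine and matrix lists and none in the activated-keratinocyte, interferon, T cell, fibroblast and cholesterol lists. Examples are Thy1 (-1.47 in females, -2.37 in males) and Krt17 (-0.53 and -1.24). Mmp3, Timp1 and Rsad2 were not above background with FA in either sex, and were at least 9.56-fold, 2.50-fold and 1.68-fold lower in males. With values set to the floor the medians were -0.48 (matrix), -0.75 (activated-keratinocyte), -0.60 (cytokines), -0.52 (interferon), -0.42 (T cell), -1.08 (fibroblast), 0.89 (sebaceous) and 2.61 (muscle). Through the high floor of female FA replicate 2, this setting by itself lowers the difference for undetected genes. Among lists that did not pass, those of anagen (0.38 to -0.19), follicle bulge (0.33 to -0.21), Y-linked genes (0.09 to -0.48) and clock genes (0.002 to -0.02) turned.

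Several of these calls were lost without single arrays. Without female FA replicate 1 the calls were lost for cornified envelope (adjusted p = 0.0528), activated-keratinocyte (0.247), cholesterol (0.0671), T cell (0.321), fibroblast (0.293), matrix (0.0671) and interferon (0.132). Without male FA replicate 1 they were lost for cholesterol (0.0821), T cell (0.0821), fibroblast (0.0821), matrix (0.0994) and interferon (0.0924). Without male vehicle replicate 1, cholesterol (0.136), T cell (0.428) and fibroblast (0.413) were lost, and without male vehicle replicate 2, activated-keratinocyte (0.409) and interferon (0.319). Without female vehicle replicate 1, cholesterol (0.0567) and interferon (0.0567) were lost, and without female vehicle replicate 2, T cell (0.0820) and interferon (0.0683). With the stricter detection filter the activated-keratinocyte, cytokine, interferon and fibroblast calls were lost, and in genes detected on all 8 arrays the first 3 of these and the matrix call. Without a filter the interferon and T cell calls were lost, with uncorrected signal the interferon call, and with array weights the T cell call. A muscle score as covariate ended the muscle call, by construction, and the interferon and T cell calls. The all-gene median of the difference moved from 0.02 to -0.21 with median scaling.

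**Figure D3:**
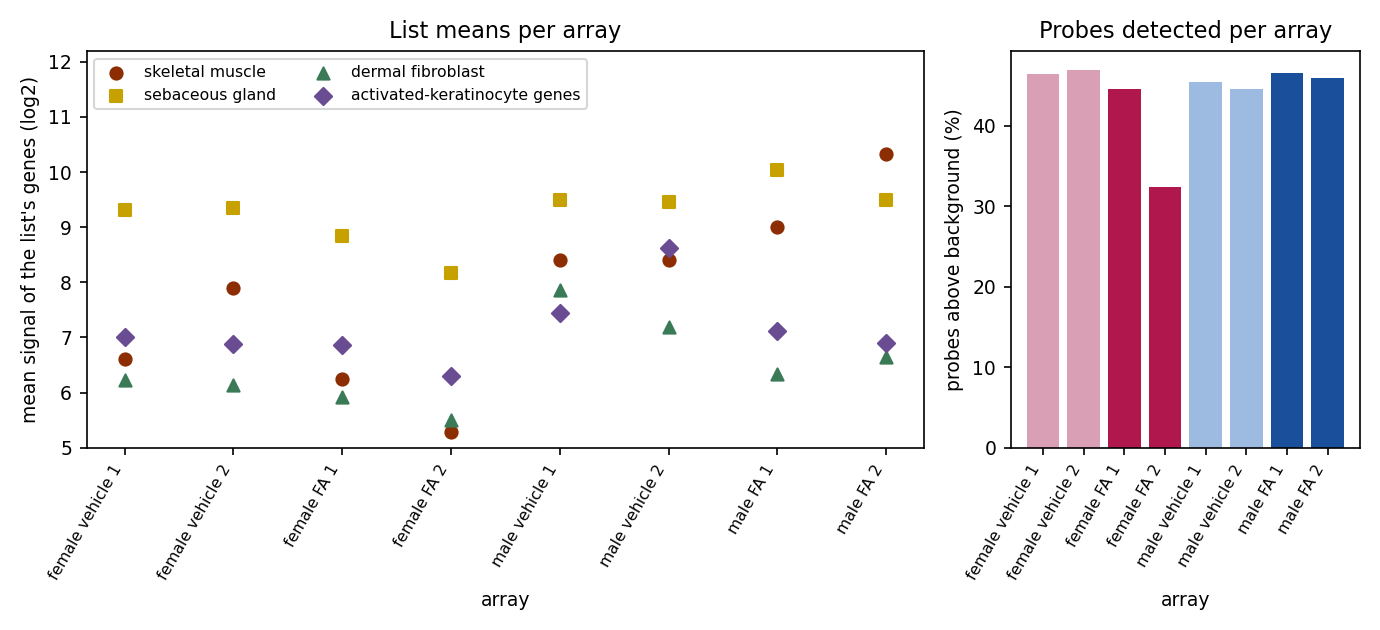
Left, mean signal (log2, y axis) of the genes of 4 lists on each of the 8 arrays (x axis); right, the percentage of probes above background on each array. Skeletal muscle ranges from 5.29 on female FA replicate 2, which had 32.4% of probes detected, to 10.32 on male FA replicate 2.

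The sexes were compared in vehicle, in mice that were shaved and given acetone, to give the dimorphism without FA. The Y-linked gene Eif2s3y was not above background in females and at least 32.7-fold higher in males, and Xist, the X-inactivation RNA, was at least 4.66-fold lower in males. Akr1c18 was 15.2-fold lower in males (log2 -3.93 ± 0.23, SE, n = 2 arrays per group), Hamp2 13.1-fold lower (-3.71 ± 0.31) and Akr1c19 7.82-fold lower (-2.97 ± 0.18). Serpina3n was 5.29-fold higher in males (2.40 ± 0.23), and Ccl4 at least 2.74-fold higher. These 7 of 9416 genes passed in limma, 3 higher and 4 lower in males. The count was 2, 3 and 2 without female vehicle replicate 1, female vehicle replicate 2 and male vehicle replicate 2, and 46 without either female FA array.

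Fibroblast markers had a median sex difference of 1.15 in vehicle (camera adjusted p = 3.00e-15; adjusted p = 0.102 with an estimated correlation; 0 of 14 passed over all genes and 11 when adjusted over the list alone); Col1a1 had 2.98 ± 0.62 and Col3a1 2.29 ± 0.46. Matrix genes had 0.40 (adjusted p = 6.22e-07; adjusted p = 0.102 with an estimated correlation; 6 of 26 when adjusted over the list alone), with Mmp3 at 2.40 ± 0.30, and activated-keratinocyte genes 0.73 (4.35e-08; 0.214 with an estimated correlation; 6 of 17), with Krt17 at 0.73 ± 0.15 and Krt6b at 3.82 ± 0.98. The mean signal of the activated-keratinocyte genes was 8.63 on male vehicle replicate 2 and 7.44 on replicate 1. On the female vehicle arrays it was 7.01 and 6.88. With the adjusted p, the same with an estimated correlation and the count adjusted over the list alone in parentheses, muscle markers had 1.18 (2.33e-08; 0.332; 0), cytokines 0.16 (0.00514; 0.118; 1), neutrophil and macrophage markers 0.43 (4.95e-04; 0.102; 2), cholesterol synthesis 0.29 (5.45e-04; 0.306; 0), cornified envelope 0.13 (0.00514; 0.181; 2) and interferon-stimulated genes 0.23 (0.0194; 0.350; 2). In the same order, the Y-linked list had 1.14 (4.73e-09; 0.102; 3), X-linked genes -0.42 (2.00e-05; 0.102; 3 lower) and clock genes -0.28 (0.0195; 0.179; 2 lower). All of these calls were lost with an estimated correlation. Over all genes these lists held Ccl4, Eif2s3y and Xist and no other passing gene. The cornified call was lost without female vehicle replicate 1 (adjusted p = 0.0528) and male vehicle replicate 2 (0.135), the clock call without the same arrays (0.0929 and 0.0666), and the interferon call without these (0.0528 and 0.372), without female vehicle replicate 2 (0.0554) and with median scaling. The stricter detection filter ended the cytokine and interferon calls, and genes detected on all 8 arrays those and the clock and matrix calls. Adding a muscle score as covariate ended the muscle, neutrophil, cornified, cytokine, interferon and clock calls, the first by construction. At the floor the Y-linked median was 0.75 and the neutrophil median 0.30. The all-gene median moved from -0.02 to 0.13 with median scaling.

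The comparison of the sexes in FA asks which genes differ after treatment. Eif2s3y was at least 23.4-fold higher in males and Xist at least 4.69-fold lower, as in vehicle. Muscle genes were far higher in males: Mylpf 24.7-fold (4.63 ± 0.43), Pvalb (5.30 ± 0.63), Myl1 (5.26 ± 0.69), Cox6a2 (3.79 ± 0.50), and Ckm, Rpl3l, Actn3 and Mybpc2 at least 12.3-fold, 8.63-fold, 6.05-fold and 4.45-fold. For none of these did the test of a changed sex difference pass. In these epidermis samples, muscle carried over into some preparations could not be told apart from a sex difference. Cidea was 6.66-fold higher (2.73 ± 0.35). Of the other genes that passed in vehicle, Serpina3n had 0.60 ± 0.23 and Hamp2 -0.87 ± 0.31, where the tests of a change did not pass (adjusted p = 0.497 and 0.328), and Akr1c18, Akr1c19 and Ccl4 were not above background in either sex. In all, 19 genes passed, 18 higher and 1 lower in males. With median scaling 4 passed, without the filter 6, with array weights 9, with replicate number as a block 10, with only the arrays of the groups compared 1 and with a muscle score as covariate 0. More passed without background correction (90), with trend and robust (73), with an offset of 50 (64), with the stricter filter (31) and with the mean of all probes (27). The count was 3, 3, 1, 1, 3 and 1 without female vehicle replicates 1 and 2, male vehicle replicates 1 and 2 and male FA replicates 1 and 2, 30 without female FA replicate 2 and 2024 without female FA replicate 1.

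With FA, the lists that passed camera at the preset correlation, each of which was lost with an estimated correlation, follow with both adjusted p in that order. They were muscle (median 3.93, camera adjusted p = 2.20e-22; 0.295; 5 of 16 higher over all genes, 15 when adjusted over the list alone), sebaceous gland (1.36, 4.00e-07; 0.295; 1 of 17, and 11 higher and 1 lower) and cholesterol synthesis (0.59, 8.04e-07; 0.295; 0 of 18, and 9). Elovl3 had 2.86 ± 0.49 and Insig1 1.47 ± 0.28. Fibroblast markers had 0.71 (3.34e-04; 0.331; 0 of 14, and 4), follicle bulge 0.72 (0.00867; 0.331; 0 of 9, and 1), anagen 0.41 (0.0355; 0.331; 0 of 7, and 3), Y-linked 1.55 (0.00108; 0.295; 1 of 3, and 2), X-linked -0.54 (8.75e-05; 0.285; 1 of 5 lower, and 2) and T cell -0.24 (0.00850; 0.295; 0 of 16, and 2 lower). Without female FA replicate 1 the calls of anagen (adjusted p = 0.208), T cell (0.218) and Y-linked genes (0.194) were lost. Anagen was also lost without female vehicle replicate 1 or 2 (0.0577 each), without male FA replicate 1 (0.0594) and with median scaling, and bulge without male FA replicate 1 (0.0762). With a muscle score as covariate the X-linked, bulge, T cell, fibroblast and muscle calls were lost, the last by construction. At the floor the medians were 3.67 (muscle), 1.09 (sebaceous), 0.45 (cholesterol), 0.42 (fibroblast), 0.49 (bulge), 0.59 (Y-linked), -0.49 (T cell) and, turned in direction, -0.21 (anagen). Here too the high floor of female FA replicate 2 lowers male minus female values of undetected genes by construction.

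**Figure D4:**
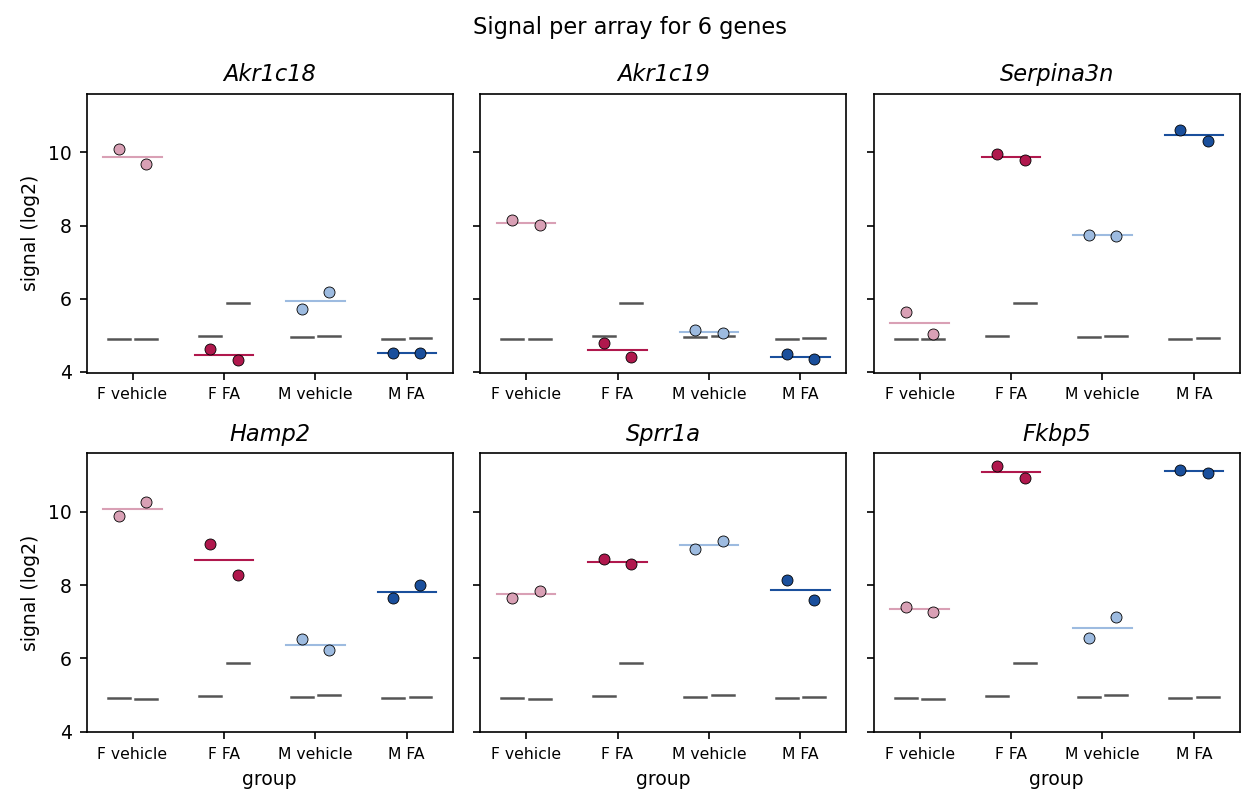
Signal (log2, y axis) of 6 genes on each array by group (x axis; F female, M male). Points are arrays, coloured lines group means of 2 arrays and grey dashes each array's floor; Akr1c18 and Akr1c19 lie below the floor on all FA arrays.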

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

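Results were examined here when the response to FA differed between females and males in a direct test, or when a signal lay in measurements the comparisons did not use. The tests of explanations below were chosen after the results were seen, except the regrouping of arrays.

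The gene differences were Akr1c18 (male minus female 3.98 on the log2 scale) and Akr1c19 (2.78). The median list differences were 2.80 for skeletal muscle, 1.12 for sebaceous gland, 0.34 for cholesterol synthesis, -0.62 for fibroblasts, -0.52 for activated-keratinocyte genes, -0.38 for interferon-stimulated genes, -0.36 for matrix and adhesion, -0.24 for cytokines, -0.23 for cornified envelope and -0.19 for dendritic epidermal T cells. None of these list differences passed with an estimated correlation between genes (adjusted p from 0.383 to 0.521). Some medians leaned on 1 male vehicle array. Without male vehicle replicate 2 the median was 0.01 for activated-keratinocyte and -0.12 for interferon-stimulated genes. Without male vehicle replicate 1 it was -0.08 for fibroblasts and -0.04 for dendritic epidermal T cells. The cause was not tested. Outside the comparisons, 119 probes with no gene name here changed with FA in the mean of both sexes in limma, 58 higher and 61 lower of 771, a share of 15.4% beside 20.8% of named genes. These probes were fitted and adjusted apart from the named genes, which had been reduced to 1 probe each. The shares are therefore not at the same threshold.

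The fitted fall of Akr1c18 and Akr1c19 was larger in females, where vehicle signals were 3.93 and 2.97 higher on the log2 scale than in males. A floor of measurement could account for this if the genes are unreadable after FA in both sexes, and 0 of the 4 FA arrays had either gene above background. A raised background on female FA replicate 2 does not account for it, since the difference without that array was 0.931 of the full one for Akr1c19 and 0.963 for Akr1c18. A sex difference in how strongly FA represses these genes, such as through female steroid metabolism, stays open as an untested biological explanation, because what happens below background was not measured.

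The skeletal muscle list had a median change with FA of -1.48 in females (0 of 16 genes passed) and 1.40 in males (1 of 16), and both calls were lost with an estimated correlation (adjusted p = 0.639 and 0.553). Muscle carried over in some preparations cannot be told apart from a difference between animals: in 3 of the 4 groups the replicate arrays differed in the list's mean beyond the 95th percentile of 10000 random lists, by 1.32 on the log2 scale in the male FA group with all 16 genes on the same side, but the list's genes vary together (estimated correlation 0.770), so such lists are no fair comparison. The raised background of female FA replicate 2 does not account for it, since the difference without that array was 0.883 of the full one. The samples are epidermis, so muscle below the skin could enter these values only through carried-over tissue. A sex difference in that muscle stays open as untested.

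The sebaceous gland list had a median change of -0.74 in females (4 of 17 genes lower and 1 higher; lost with an estimated correlation, adjusted p = 0.639, and without female vehicle replicate 2, 0.0646) and 0.12 in males. The share of the difference left without female FA replicate 2 was 0.621, so a partial effect of its raised background cannot be told apart from a sex difference. A larger share of hair follicle in some preparations cannot be told apart either: bulge and upper follicle genes outside the list differed by a mean of 0.12 ± 0.20 (SE over 8 genes) against 1.13 ± 0.25 for sebaceous genes (17), but 6 of the 8 had a value below an array's floor. A sex difference in the gland's response to FA, possibly through androgens, stays open as untested.

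The role of chance in the count of FA-changed genes was tested by regrouping the 8 arrays in all 35 ways of 4 against 4, with sex as a covariate except in the grouping equal to sex, where it could not be fitted. The real grouping gave 1960 genes and the highest other grouping, the one equal to sex, 2, so 1 grouping of the 35 reached the real count. In the other groupings the FA effect stays in the residual spread, which lowers their counts, so these do not measure the number of false calls. The test was not run within 1 sex, where too few groupings exist.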

How the results depend on the processing

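No named gene call passed in the opposite direction under any alternative. Some list medians turned, several of which are given in the comparisons. Counts beyond 1.5 times the reported one, up or down, follow, and the cause was not tested unless the alternative's construction gives it. The muscle covariate and the genes detected on all 8 arrays were chosen after the data were seen. The latter leave out genes that FA took below background, so their shift towards rises is in part by construction.

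Genes changed by FA in females and males, in that order, numbered 1535 and 1317 with uncorrected signal and 506 and 1454 with array weights. They numbered 1502 and 1280 with trend and robust in limma's eBayes, and 193 and 1282 with only the arrays of the groups compared. With a skeletal muscle score as a covariate they numbered 146 and 150, and 1794 genes passed in the mean of both sexes. The score takes up a degree of freedom, as does the replicate block, which left 837 and 677 in females and males. The score also moved with FA within each sex, in opposite directions, so it cannot be fully separated from these effects. With at least 2-fold change required, which by construction removes genes, 608 passed in females and 629 in the mean of both sexes. More genes passed as higher than as lower in genes detected on all 8 arrays (686 and 575 in females, 554 and 486 in males, 1087 and 964 in the mean), and in females with median scaling (565 and 450), without vehicle replicate 1 (111 and 105) and without FA replicate 2 (413 and 409). In males this held without FA replicate 2 (137 and 105) and with the muscle covariate (81 and 69).

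Genes whose response differs numbered 5 with uncorrected signal, 7 with trend and robust, 1 with detection p under 0.01 on at least 4 arrays, and 0 with median scaling, without the filter, with the replicate block, with the muscle covariate and in genes detected on all 8 arrays, which leave out Akr1c18 and Akr1c19 by construction.

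Genes that differ between sexes in vehicle numbered 15 with uncorrected signal, 11 with offset 50, 23 with array weights, 15 with trend and robust, 4 with the muscle covariate, 2 in genes detected on all 8 arrays and 89 with only the arrays of the groups compared. In FA they numbered 90 with uncorrected signal, 4 with median scaling, 64 with offset 50, 6 without the filter, 31 with the stricter filter, 10 with the replicate block, 9 with array weights, 73 with trend and robust, 0 with the muscle covariate and 1 with only the arrays of the groups compared.

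Lists that changed numbered 1 in females, 1 in males, 0 for the difference and 0 for sex in vehicle with camera at an estimated correlation. With fry they numbered 7 in males, 1 for the difference and 7 for sex in vehicle. In genes detected on all 8 arrays they numbered 4 in males, 6 for the difference and 5 for sex in vehicle, where 6 passed with the muscle covariate.

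Leaving out 1 array at a time, with the lone array left in a group assumed to vary like the other groups, the counts ranged from 216 to 3004 (females), 208 to 1497 (males), 0 to 1135 (difference), 1008 to 3585 (mean of both sexes), 2 to 46 (sex in vehicle) and 1 to 2024 (sex in FA). The list counts ranged from 6 to 9, 10 to 13, 3 to 13 and 9 to 13 for females, males, the difference and sex in vehicle. The correlation between the sexes' effects ranged from 0.517 to 0.756 and the ratio of sizes from 0.683 to 1.47.

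Arrays with the same replicate number correlated, after group means were removed, between -0.03 and 0.23, and fitting the number as a replicate block spends degrees of freedom. The slide was not fitted as a block, since the sources used here name no slide. Of 318 calls of named genes, median scaling kept 288, uncorrected signal 310, offset 50 314, no filter 275 and the muscle covariate 189, only the arrays of the groups compared kept 145 of 204, and leaving out 1 array kept 214 to 316. Signal over background limits what can be read on female FA replicate 2, where 32.4% of probes were detected. Array weights could not lower the weight of that array alone, since both arrays of a group received the same weight. For both female FA arrays it was 0.443, the lowest of any group.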

Other observations

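The gene families below were chosen after the data were seen, from a larger set that was tested. Of the others, aldo-keto reductases (camera adjusted p = 4.54e-04 in females, 0.0146 in males) and cytosolic ribosomal proteins (0.0133 and 0.0323) were lower with FA. Serpins were higher in males in vehicle (camera adjusted p = 4.25e-07). These calls were lost with an estimated correlation. Further families passed between the sexes. Nuclear genes of oxidative phosphorylation had a median of -0.51 with FA in females (69 genes, 16 lower, none higher, camera adjusted p = 2.56e-09) and -0.32 in males (3 lower, adjusted p = 3.22e-05), with Ndufa1 at -1.28 and -0.86, Uqcr11 at -1.10 and -0.74 and Atp5g1 at -1.09 and -0.80. These calls were lost with an estimated correlation (adjusted p = 0.144 and 0.148). The family was higher in males as a difference of FA effects (0.20, adjusted p = 0.0153; 0.372 with an estimated correlation) and between sexes in FA (0.20, adjusted p = 1.36e-05; 0.396), the direction of skeletal muscle markers, whose medians with FA were -1.48 in females and 1.40 in males. Cytochrome P450 genes had medians of 0.32 (17 genes, 4 higher, adjusted p = 0.00222) and 0.84 (6 higher, adjusted p = 5.00e-05), with the xenobiotic enzyme genes Cyp2b10 at 2.89 and 2.96, Cyp2b23 at 1.57 and 2.45 and Cyp2a5 at 1.87 and 1.46; both were lost with an estimated correlation (adjusted p = 0.144 and 0.148).

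Proteasome genes had medians of -0.31 (34 genes, 3 lower, adjusted p = 6.08e-04) and -0.23 (3 lower, adjusted p = 7.51e-04), lost with an estimated correlation (adjusted p = 0.225 and 0.247). The immunoproteasome gene Psmb10 fell in both sexes (-1.40 and -1.95). Wnt and Hedgehog genes had medians of -0.62 (9 genes, 3 lower, adjusted p = 0.00721) and -0.80 (none past the threshold over all genes, adjusted p = 0.00170), among them Wnt3 (at least 2.17-fold lower in females, -0.80 in males), and were lost with an estimated correlation (adjusted p = 0.144 and 0.148). Collagen genes had medians of -0.46 and -0.57 (18 genes; 3 lower in females, 4 lower and 1 higher in males), with Col18a1 at -2.82 and -2.88 and Col23a1 at least 2.59-fold lower in females and at -1.65 in males; the family passed in males (adjusted p = 0.0323; 0.262 with an estimated correlation) and not in females (adjusted p = 0.420). Histone genes, which have near-identical paralogs, went both ways, with 2 higher and 8 lower of 36 in females and 3 higher and 8 lower in males.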
